A study of Mus musculus with 6 samples.

How the data were processed

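The data are RNA sequencing of mammary tumours from MMTV-PyMT mice, a transgenic strain in which the polyoma virus middle T antigen is driven in the mammary epithelium by the mouse mammary tumour virus promoter. There were 3 libraries from mice given an agonist of the liver X receptors (LXR) and 3 from mice given vehicle, each with its own table of 55487 gene rows. The groups were taken from the treatment label of each sample and the replicate numbers from its title.

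The deposited tables hold RSEM expected counts, estimated read counts per gene that need not be whole because a read that matches several transcripts is shared among them. They also hold TPM, which the authors' RSEM run computed from the same reads after division by transcript length. Another measure in the deposited tables, FPKM, was not used here. The submitters' processing notes name FastQC 0.11.9, cutadapt 3.5, STAR 2.7.9a, RSEM 1.3.1, DESeq2 1.36.0 and R 4.1 with the genome build GRCm38. The annotation release, the strand setting and any read filter are not given in the sources used here. Without a stated strand setting, reads of overlapping genes and of antisense partners cannot be told apart, and counts split among near-identical copies, such as the protocadherin alpha genes, the Dcpp genes and immunoglobulin segments, are uncertain. Gene positions are those of GENCODE M21 on GRCm38, in which 55227 of the 55487 row identifiers were found.

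Over all gene rows, including those without reads, between 10.1% and 10.5% of the expected counts were not whole in each library. All were rounded to whole numbers before testing. Each library summed to between 36577451 and 42595799 expected counts. At this depth 3 counts correspond to between 0.0704 and 0.082 CPM scaled to the library total, a floor that covers counting error alone, as PCR copies were not told apart by molecular identifiers. The main test was edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr at its defaults (minimum count 10, minimum total count 15), robust dispersion estimates and the quasi-likelihood F test of group, without covariates. This left 17396 genes. Adjusted p-values are Benjamini-Hochberg values over those genes and were called under 0.05. Standard errors are the log2 fold change divided by the square root of its F statistic, and SDs are over the 3 libraries of a group on the CPM scale. CPM are counts scaled to the TMM-adjusted total of the tested genes, except for the floor, the exocrine, salivary and plasma cell comparisons and the protocadherin sums, which include untested genes and are scaled to the plain library total.

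Before the data were examined, 33 gene lists with 531 distinct genes, of which 480 were tested, were written for LXR targets, lipid pathways, proliferation, interferon and stress responses, and the cell types that a mammary tumour piece can hold. A list was tested with camera (limma 3.58.1) on the edgeR fit, which asks whether its members moved relative to all other genes, with the tool's preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 33 lists. The correlation that camera estimated from these libraries had a median of 0.474 over the lists, far above the preset. Each call of the main fit is therefore also given with the estimated correlation, and fry was run on that fit as well. In the alternative settings lists were called with the preset correlation only. Fry asks whether a list's genes move, on balance, one way. A library's score for a list is the mean deviation of the list's genes from their mean over the 6 libraries, in log2 CPM with a prior count of 2. Differences of scores between groups were tested with a two-sided exact permutation test, which cannot give a p below 0.1 with 3 libraries against 3.

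The rule for naming genes was also fixed beforehand. It takes up to 12 genes per direction by size among those with an adjusted p under 0.05, a mean log2 CPM of at least 1 and groups that do not overlap, which gave 0 genes. It also takes the 4 members of each list with the smallest unadjusted p and 13 genes chosen in advance, among them Abca1, Abcg1, Srebf1, Mylip, Scd1, Fasn, Nr1h2, Nr1h3, Mki67, Epcam and Ptprc. The last 2 parts of the rule take 140 genes, some of which are not reported here. Any gene named outside the rule is said to have been chosen after its values were seen.

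The alternatives fixed in advance were DESeq2 size factors, upper-quartile factors, no low-count filter, a stricter filter (a CPM of at least 1 in at least 3 libraries), no robust estimation, the replicate number as a block, each library left out in turn, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, and limma-trend on log2(TPM + 1). Further alternatives were chosen after seeing the data, namely a GC correction, in which a loess curve (span 0.3) of each library's deviation on transcript GC content entered the fit as an offset, removal of one ribosomal RNA row, and the fibroblast and matrix score as a covariate. No pair of libraries matched within sampling noise, with a chi-square per degree of freedom between 73.3 and 299 over all pairs.

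The procedure was tested on simulated data drawn from the means and dispersions of these 6 libraries with 200 genes changed. In 17046 simulated genes that passed the filter, edgeR recovered 26% of the genes changed 2-fold and 80% of those changed 4-fold, with 15 false calls. DESeq2 recovered 53% and 96.0% in 17382 genes, with 81 false calls. Limma-voom recovered 23% and 78%, with 11 false calls. A simulated list of 20 shifted genes was called by camera with either correlation and by fry (p = 3.38e-27, 0.000295 and 9.59e-05), and a list of 20 unchanged genes was not (p = 0.524, 0.611 and 0.561). Each simulated gene was drawn independently, whereas the real lists had a median estimated correlation of 0.474. The simulation therefore does not show how often these list tests miss or wrongly call a list of correlated genes.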

Results

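Mammary tumours of MMTV-PyMT mice were profiled by RNA sequencing to follow how activation of LXR bears on tumour progression. The libraries came from 3 tumours of mice that took DMHCA, a steroidal LXR agonist, by mouth in gel cups without interruption from an age of 6 weeks, and from 3 tumours of vehicle mice. The agonist libraries summed to 36577451, 40159352 and 41434703 expected counts and the vehicle libraries to 42595799, 39977825 and 40680106. The labels do not say that the tumours of a group came from separate mice. All titles of a group share 1 code, which differs between the groups and is not explained, while the deposited tables carry a code per library, so a single source per group cannot be told apart from treatment. The p-values measure the spread between these samples, which may be technical in part.

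The comparison of agonist and vehicle tumours asks which genes respond to LXR activation, and the 2 cholesterol exporters that are classical direct LXR targets were higher in all 3 agonist libraries than in any vehicle library. Abcg1, on chromosome 17 (31057675 to 31117988, plus strand), had 36.8 ± 5.28 CPM with agonist and 20.3 ± 5.44 with vehicle (SD, n = 3), a log2 fold change of 0.86 ± 0.23 (SE; 95% interval 0.32 to 1.39). Abca1, on chromosome 4 (53030787 to 53159895, minus strand), had 118 ± 18.1 against 65.7 ± 30.2 CPM, a log2 fold change of 0.85 ± 0.31 (0.11 to 1.58). The lowest agonist library had 100.2 CPM of Abca1 and vehicle replicate 2 had 99.9, a margin far within the spread between libraries. The stearoyl-CoA desaturases Scd1 (log2 fold change 1.06 ± 0.47) and Scd2 (0.61 ± 0.22) also had higher means with agonist, while Mlxipl, which encodes the lipogenic factor ChREBP, had a lower one (-0.75 ± 0.29). With libraries left out, the log2 fold change of Abca1 ran from 0.61 (vehicle replicate 1) to 1.28 (vehicle replicate 2). That of Abcg1 ran from 0.65 to 1.01 with the same libraries left out. Scd1 ran from 0.54 (agonist replicate 2) to 1.48 (vehicle replicate 2). Neither exporter passed the threshold over all genes tested, with an adjusted p of 0.99 by edgeR and unadjusted p of 0.00644 for Abcg1 and 0.0288 for Abca1.

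**Figure D1:**
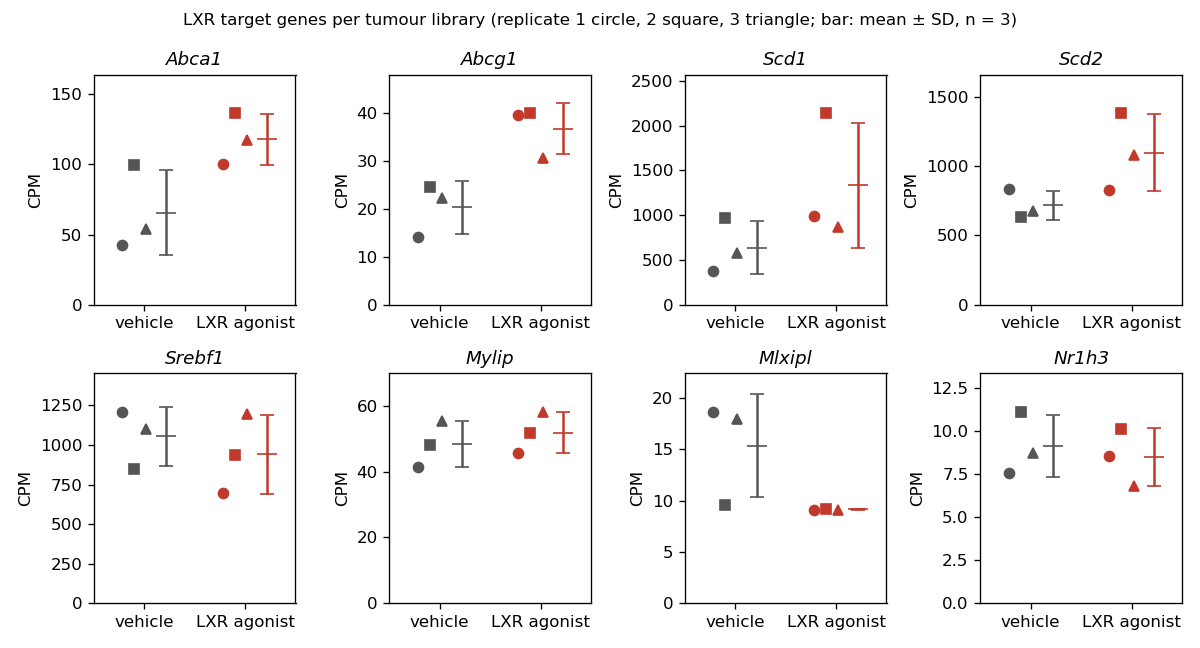
CPM (vertical axes, linear from 0) of 8 LXR target genes in the 3 vehicle (grey) and 3 agonist (red) libraries, with symbols for replicates 1 to 3 and bars for the mean ± SD (n = 3). All 3 agonist libraries lie above all 3 vehicle libraries for Abca1 and Abcg1, whereas the groups overlap for Scd1, Scd2, Srebf1, Mylip and Nr1h3, and Mlxipl lies lower in the agonist libraries.

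Of the 19 LXR target genes on the list, 16 were tested, 13 had positive and 3 negative log2 fold changes, and the median was 0.20. The list was called higher by camera with its preset correlation (adjusted p = 0.000982), and adjusted p = 0.641 with an estimated correlation. Members changed numbered 0 both over all genes and adjusted over the list alone. Other established targets stayed near their vehicle level. Srebf1, the master regulator of fatty acid synthesis, had 942 ± 250 CPM against 1055 ± 185 (log2 fold change -0.16 ± 0.24), and Mylip, which encodes a ubiquitin ligase, had 51.8 ± 6.19 against 48.3 ± 6.97 (0.10 ± 0.16). The receptors themselves, Nr1h3 (LXRα, -0.11 ± 0.27) and Nr1h2 (LXRβ, -0.26 ± 0.18), were within the spread between libraries. With libraries left out Srebf1 ran from -0.37 (agonist replicate 3) to 0.0136 (agonist replicate 1), Mylip from 0.0033 (vehicle replicate 1) to 0.22 (vehicle replicate 3), Nr1h3 from -0.25 (agonist replicate 2) to 0.056 (vehicle replicate 2) and Nr1h2 from -0.41 (vehicle replicate 2) to -0.17 (vehicle replicate 3). The list score of vehicle replicate 2 was 0.32, above the agonist scores of 0.14 to 0.26, and without vehicle replicate 3 the list's adjusted p was 0.0611.

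Across all 17396 genes, 0 passed an adjusted p of 0.05 in the edgeR test, and the smallest adjusted p was 0.99. At an unadjusted p under 0.05 there were 538 genes, 125 higher and 413 lower with agonist, fewer than the 870 that chance alone gives. The split was 182 higher and 331 lower with upper-quartile scaling. The groups did not overlap for 526 genes higher and 734 lower with agonist, 7.24% of the genes, where chance gives 10% for 3 libraries against 3. DESeq2 called 5 genes and had 772 at an unadjusted p under 0.05, limma-voom called 0 and had 1210, and limma-trend on TPM called 0 and had 375. Leaving out vehicle replicate 2 gave 2442 genes at an unadjusted p under 0.05 and leaving out agonist replicate 3 gave 315, with 0 at an adjusted p of 0.05 in either fit.

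The 5 genes called by DESeq2 are named here after their values were seen. In the simulation DESeq2 made 81 false calls, against 15 by edgeR. It recovered 53% of 100 genes changed 2-fold and 96.0% of 99 changed 4-fold. The false calls were thus a larger share of its calls than the adjusted p threshold allows. The same held, to a lesser degree, for edgeR and limma-voom. The DESeq2 adjusted p-values below are therefore likely too small and do not establish a change on their own. Arrb1, which encodes beta-arrestin 1, a regulator of G protein-coupled receptors, had 34.5 ± 1.74 CPM with agonist and 66.9 ± 1.04 with vehicle, a log2 fold change of -0.96 (DESeq2 adjusted p = 0.00109). The gene lies on chromosome 7 (99535466 to 99606771, plus strand), and its edgeR adjusted p was 0.99 at an unadjusted p of 5.77e-05. Pcdha8, a member of the clustered protocadherins, had 3.17, 2.26 and 0.671 CPM in the vehicle libraries and 0.135, 0.0732 and 0 in the agonist libraries (DESeq2 adjusted p = 0.000732). Its annotated span on chromosome 18 (36992371 to 37187657) is shared with its neighbours in the cluster, so its counts are uncertain. The lincRNA Gm26964 was detected at 0.755 ± 0.211 CPM with vehicle and 0.00796 ± 0.0138 with agonist (adjusted p = 0.0205). The immunoglobulin kappa constant gene Igkc was higher with agonist (DESeq2 log2 fold change 3.93, adjusted p = 0.0207). By edgeR it was at 3.91, and at 2.40 without agonist replicate 2. Prpmp5, which encodes a proline-rich secreted protein, had a DESeq2 log2 fold change of 7.43 (adjusted p = 0.0172). It did not pass the edgeR filter, so too few libraries reached the count cutoff to read that value as a difference between the groups.

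In the lipid pathways, the 21 genes of fatty acid and triglyceride synthesis gave a median log2 fold change of 0.02, with 11 positive and 10 negative (camera adjusted p = 0.453). Within it Acsl3, an acyl-CoA synthetase, had 73.4 ± 16.7 CPM against 45.1 ± 6.4 (0.70 ± 0.20) and was higher in all 3 agonist libraries, while Pnpla3, a lipase of lipid droplets, was lower in all 3 (-1.45 ± 0.45) and Fasn, fatty acid synthase, was at -0.23 ± 0.17, with -0.11 without agonist replicate 1 and -0.36 without agonist replicate 2. The list was called higher without agonist replicate 1 (adjusted p = 0.0318). Of the 24 tested genes of cholesterol synthesis and uptake, 10 were positive and 14 negative (median -0.02, adjusted p = 0.923). Srebf2, the master regulator of that pathway, had a log2 fold change of -0.66 ± 0.27, and of -0.37 without vehicle replicate 1. Genes of fatty acid oxidation rose as a list, with 15 of 17 positive and a median of 0.25 (camera adjusted p = 0.00213), and adjusted p = 0.641 with an estimated correlation. Acadl (0.53 ± 0.25) and Cpt1a (0.52 ± 0.26), which act in the entry and breakdown of long-chain fatty acids, had the smallest unadjusted p, and they were at 0.87 and 0.85 without vehicle replicate 2 and at 0.34 and 0.37 without vehicle replicate 1. The list's scores in vehicle replicates 2 and 3 (0.39 and -0.58) lay apart in the same direction as those of the fibroblast list (1.17 and -1.82), and its adjusted p was 0.0700 with the fibroblast score as a covariate, chosen after seeing the data. The adjusted p was 0.152 without vehicle replicate 3 and 0.0555 without agonist replicate 1.

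The mitosis list rose with agonist in the camera test, with 20 of 21 genes positive and a median of 0.32 (adjusted p = 6.13e-07), and adjusted p = 0.641 with an estimated correlation. Cdk1, the kinase that drives entry into mitosis, had 86.2 ± 2.69 CPM against 63.3 ± 11.6 (0.45 ± 0.16), and the kinetochore motor Cenpe (0.37 ± 0.14) and the cyclin Ccnb2 (0.34 ± 0.17) were likewise higher in all 3 agonist libraries. Mki67, the proliferation marker, had 428 ± 155 against 350 ± 78.6 CPM (0.29 ± 0.29), with 0.0148 without agonist replicate 3, 0.17 without vehicle replicate 1, 0.48 without vehicle replicate 2 and 0.54 without agonist replicate 1. DNA replication genes were positive in 18 of 22 cases (median 0.18, camera adjusted p = 0.00201), and adjusted p = 0.641 with an estimated correlation, with Ccne1 at 0.49 ± 0.22 and Mcm4 at 0.36 ± 0.19 (0.23 without vehicle replicate 1). Without vehicle replicate 3 the replication list's adjusted p was 0.143.

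Interferon-stimulated genes fell as a list, with 21 of 23 negative and a median log2 fold change of -0.64 (camera adjusted p = 6.13e-07), and adjusted p = 0.641 with an estimated correlation. The antiviral genes Oasl2 (-1.70 ± 0.68) and Mx2 (-1.09 ± 0.49), the interferon regulator Irf7 (-1.15 ± 0.51) and the nucleic acid sensor Zbp1 (-0.79 ± 0.35) were the negative members with the smallest unadjusted p. Without vehicle replicate 1 they were at -0.76, -0.69, -0.50 and -0.29. The list score was 0.88 in vehicle replicate 1 and 0.37 in vehicle replicate 3, but -0.43 in vehicle replicate 2, within the agonist range of -0.70 to 0.12. MHC class I presentation genes were negative in 10 of 12 cases (median -0.29, camera adjusted p = 0.0292), and adjusted p = 0.641 with an estimated correlation, with Tapbp, a peptide-loading chaperone, at -0.61 ± 0.27 and H2-T23 at -0.44 ± 0.17. Without vehicle replicate 1 Tapbp was at -0.21. Vehicle replicate 1 alone had a positive vehicle score for that list (0.73), and without it the list's direction turned (adjusted p = 0.232). That call also ended without agonist replicate 1 (0.0724), without agonist replicate 2 (0.368) and with the GC correction (0.0882). MHC class II genes (median -0.19, 6 of 10 negative, adjusted p = 0.420) included H2-DMb1 at -1.03 ± 0.32, and at -0.60 without vehicle replicate 1. That list was called lower without vehicle replicate 3 (9.96e-05) and with the fibroblast score as a covariate (0.00103).

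Hypoxia and glycolysis genes fell together in the camera test, with 15 of 16 negative and a median of -0.31 (adjusted p = 2.84e-06), and adjusted p = 0.641 with an estimated correlation. Ndrg1, a hypoxia-induced gene, had 87.4 ± 15.6 CPM against 180 ± 76.1 (-1.04 ± 0.31), and Vegfa, the angiogenic growth factor, had 77.2 ± 16.1 against 160 ± 79.9 (-1.05 ± 0.35). Both were lower in all 3 agonist libraries, with Ndrg1 at -0.68 without vehicle replicate 2 and Vegfa at -0.56 without vehicle replicate 3. Ldha (-0.47 ± 0.21) and the glucose transporter Slc2a1 (-0.50 ± 0.23, and -0.30 without agonist replicate 3) had overlapping groups, and the list score of agonist replicate 1 (0.13) lay within the vehicle range of 0.05 to 0.40. Immediate early and heat shock genes were negative in 10 of 13 cases (median -0.29, camera adjusted p = 0.0185), and adjusted p = 0.641 with an estimated correlation, with Fosb at -1.78 ± 0.71 (-0.64 without vehicle replicate 2) and Ier2 at -0.30 ± 0.14. Their call ended without vehicle replicate 1 (adjusted p = 0.187), without vehicle replicate 2 (0.263), without agonist replicate 2 (0.127) and with the GC correction (0.159). The unfolded protein and integrated stress response (median -0.12, adjusted p = 0.263; Ddit3 at -0.47 ± 0.22) and NRF2 targets (median -0.03, adjusted p = 0.982; Txn1 at 0.30 ± 0.16) were not called.

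Among the epithelial lists, basal and myoepithelial genes rose, with 11 of 12 positive and a median of 1.04 (camera adjusted p = 1.02e-06), and adjusted p = 0.641 with an estimated correlation. The smooth muscle genes Myh11 (2.76 ± 1.07), Actg2 (2.20 ± 0.91) and Acta2 (1.91 ± 0.77) and the basal collagen Col17a1 (1.35 ± 0.57) led the list. Most of that difference lay in agonist replicate 3, whose list score was 1.68 against 0.10 and -0.28 in agonist replicates 1 and 2, and without it Myh11 was at 0.57, Actg2 at 0.81, Acta2 at 0.90 and Col17a1 at 0.74 and the list's adjusted p was 0.025. Luminal epithelial genes were negative in 16 of 20 cases (median -0.25, camera adjusted p = 0.0191), and adjusted p = 0.641 with an estimated correlation. The luminal transcription factors Elf3 (-0.62 ± 0.19) and Gata3 (-0.46 ± 0.25) and the tight junction gene Cldn3 (-0.44 ± 0.22) were among them, whereas Epcam, the general epithelial marker, was at 942 ± 96 against 866 ± 60.2 CPM (0.12 ± 0.15). Gata3 was at -0.26 without agonist replicate 2 and -0.27 without vehicle replicate 1, and Epcam at 0.0402 without agonist replicate 1. The luminal call ended without agonist replicate 2 (adjusted p = 0.0902), vehicle replicate 2 (0.225) or vehicle replicate 3 (0.183) and with the GC correction (0.159). Milk protein and secretory genes went both ways, 8 positive and 8 negative, with a median of -0.02 and a mean of -0.11 although camera placed the list higher (adjusted p = 0.923, and 0.00173 without vehicle replicate 2). Lalba, the alpha-lactalbumin gene, had 286 ± 97.2 CPM against 533 ± 50.6 and was lower in all 3 agonist libraries (-0.90 ± 0.27), while the casein Csn1s2a varied too widely to compare (-1.04 ± 1.06, and 0.96 without vehicle replicate 2).

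Fibroblast and matrix genes were positive in 18 of 20 cases with a median of 0.24 (camera adjusted p = 0.0014), and adjusted p = 0.641 with an estimated correlation. The vehicle scores for this list ran from -1.82 in replicate 3 to 1.17 in replicate 2, wider than the agonist range of 0.08 to 0.64, and without vehicle replicate 3 the direction turned (adjusted p = 0.545). Postn, the matrix gene periostin, had 796 ± 193 CPM against 530 ± 542, with a log2 fold change of 0.12 without vehicle replicate 3, 0.35 without vehicle replicate 1 and 1.82 without vehicle replicate 2. The genes of epithelial-mesenchymal transition followed the same libraries, with 10 of 14 positive, a median of 0.10 and a camera adjusted p of 0.0412, and adjusted p = 0.641 with an estimated correlation. They also turned without vehicle replicate 3 (0.545), and that call ended without agonist replicate 1 (0.197), without agonist replicate 3 (0.0716) and with upper-quartile scaling (0.0575). Endothelial genes were positive in 15 of 16 cases (median 0.30, adjusted p = 0.00421), and adjusted p = 0.641 with an estimated correlation. Eng, an endothelial receptor, was at 0.52 ± 0.40, with 0.23 without vehicle replicate 3, 0.26 without agonist replicate 2 and 0.84 without vehicle replicate 2. Without vehicle replicate 3 the endothelial adjusted p was 0.314 and without agonist replicate 1 it was 0.221. Skeletal muscle genes, which a mammary fat pad specimen can carry from the body wall, were positive in 15 of 15 cases (median 0.23, adjusted p = 0.000982; Myh4 at 0.50 ± 0.25, and 0.27 without vehicle replicate 1), and adjusted p = 0.641 with an estimated correlation. The muscle call ended without agonist replicate 1 (0.462) or vehicle replicate 3 (0.0523). With the fibroblast score as a covariate, chosen after seeing the data, the calls of endothelial (0.304), muscle (0.0771), fatty acid oxidation and ribosomal protein genes (0.0700 each) ended. The epithelial-mesenchymal transition call also ended there, and its direction turned. The fibroblast list's own call ended too (0.924), an outcome fixed in advance because the covariate was made from its genes. Adipocyte genes were not called (median -0.31, 10 of 16 negative, adjusted p = 0.923), but were called lower without vehicle replicate 3 (0.00183) and with that covariate (0.000118), and higher without vehicle replicate 2 (0.0024).

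Leukocyte markers were low throughout, and Ptprc, the pan-leukocyte gene CD45, had 31.5 ± 4.2 CPM with agonist and 24.2 ± 12.2 with vehicle (0.38 ± 0.37, 0.06 without vehicle replicate 3 and 0.79 without vehicle replicate 2). The B and plasma cell list, with 6 of its 15 genes tested and 5 positive, was called higher (median 0.62, camera adjusted p = 0.00161), and adjusted p = 0.641 with an estimated correlation. Adjusted over the list alone, 2 of its members rose, Igkc (4.91 ± 5.53 against 0.327 ± 0.318 CPM, log2 fold change 3.91 ± 1.09) and Jchain, the joining chain of secreted antibodies (2.83 ± 2.85 against 0.386 ± 0.227 CPM, 2.87 ± 0.86), both with adjusted p = 0.0327, and 0 rose over all genes tested. Igkc and Jchain were higher in all 3 agonist libraries, most of all in agonist replicate 2, without which their log2 fold changes were 2.40 and 1.64. Exocrine gland transcripts, chosen after their values were seen, were high in the same library, with a median log2 ratio to the mean of the other 5 libraries of 3.83 over 7 genes (7.59 for Pip), against 3.47 for the plasma cell genes Igkc, Igha and Jchain. Igha was likewise chosen after its values were seen. The B and plasma cell list lost its call without a low-count filter (0.0702) and with the stricter filter (0.0816), which test other members. Lists not called were macrophages (median 0.14, 14 of 20 positive, adjusted p = 0.0638), neutrophils and granulocytic myeloid cells (median 0.21, adjusted p = 0.0534), T and NK cells (median 0.03, adjusted p = 0.453), regulatory T cells and checkpoints (median 0.26, adjusted p = 0.106) and inflammatory cytokines and chemokines (median 0.04, adjusted p = 0.437). Dendritic cell genes were also not called (adjusted p = 0.245), with a median of -0.04 but a mean of 0.04. With an estimated correlation the adjusted p of these uncalled lists was 0.641 to 0.835 in the main fit. Several of them were called higher in other settings, where only the preset correlation was used. Without a low-count filter these were T and NK cells and regulatory T cells (0.0137 each) and neutrophils (0.0195), and with the stricter filter neutrophils (0.0305) and macrophages (0.0429). With the GC correction they were macrophages (0.0154) and neutrophils (0.0497). Without vehicle replicate 2 they were macrophages (6.08e-08), dendritic cells (0.00582), cytokines (0.00934), neutrophils (0.0201) and T and NK cells (0.0441). Without vehicle replicate 1 they were regulatory T cells (0.00319) and T and NK cells (0.0109), without agonist replicate 1 T and NK cells (0.00405), macrophages (0.0318) and regulatory T cells (0.0444), and without agonist replicate 3 neutrophils (0.0260) and macrophages (0.0466).

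Ribosomal protein genes were positive in 20 of 20 cases by small amounts (median 0.15, camera adjusted p = 0.00387; Rpl3 at 0.25 ± 0.17), and adjusted p = 0.641 with an estimated correlation. Mitochondrially encoded mRNAs were positive in 12 of 13 cases (median 0.18, camera adjusted p = 0.0246; mt-Nd1 at 0.23 ± 0.20), and adjusted p = 0.641 with an estimated correlation. Rpl3 was at 0.39 without vehicle replicate 2, and mt-Nd1 at 0.105 without vehicle replicate 1 and 0.40 without vehicle replicate 3. The ribosomal call ended without vehicle replicate 1 (0.0710), agonist replicate 1 (0.0836) or agonist replicate 3 (0.0581), and the mitochondrial call without vehicle replicate 1 (0.691), vehicle replicate 2 (0.210) or agonist replicate 1 (0.253) and with the GC correction (0.784). Skin keratinocyte genes (median 0.22, adjusted p = 0.130), erythroid genes (median -0.21, adjusted p = 0.0509) and Schwann cell and nerve genes (median -0.21, adjusted p = 0.213) were not called. Erythroid genes lay close to the threshold and were called lower in several other settings, among them the stricter filter (0.0429) and the fits without agonist replicate 1 (9.77e-11) or vehicle replicate 3 (0.0122). Keratinocyte genes were called higher without a filter (0.038), without vehicle replicate 2 (0.00794) or agonist replicate 2 (0.0159) and with the GC correction (0.0472), and nerve genes lower with the stricter filter (0.0429). In the nerve list, Sox10, which mammary progenitor-like cells also express, had 330 ± 99.6 CPM against 647 ± 195 (-0.97 ± 0.31), and Mbp had 29.3 ± 1.94 against 39.8 ± 5.65 (-0.44 ± 0.16). Both were lower in all 3 agonist libraries.

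**Figure D2:**
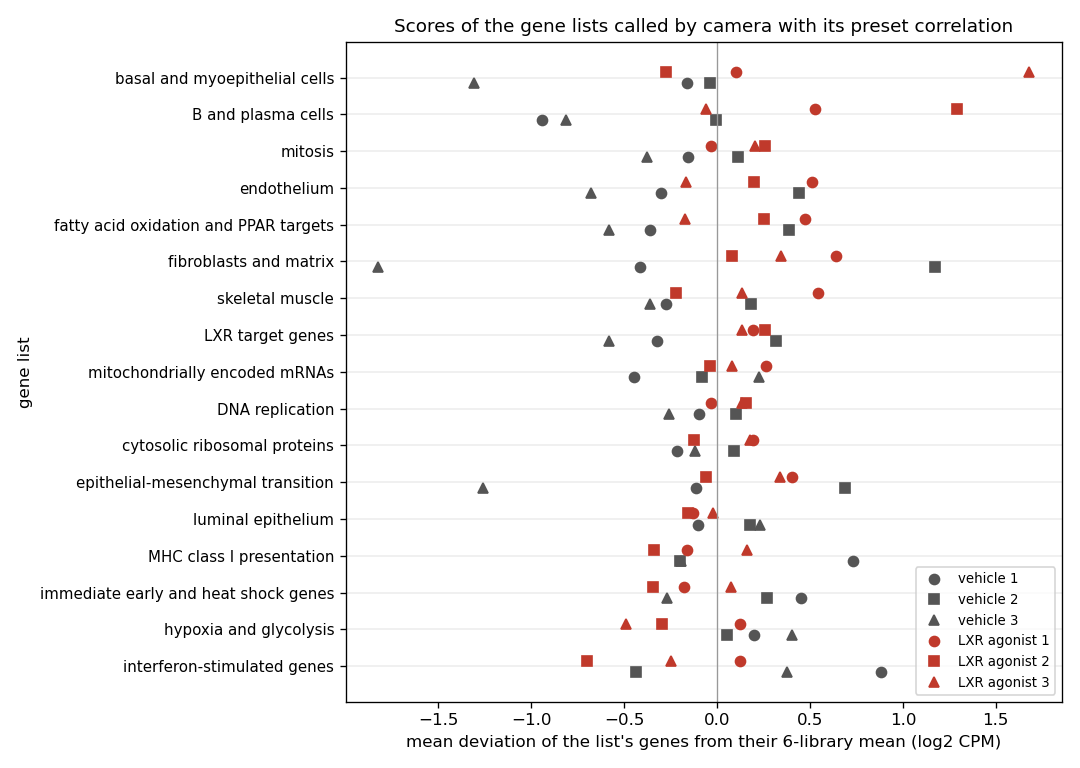
Score of each of the 17 gene lists called by camera with its preset correlation (rows) in the 6 libraries, as the mean deviation of the list's genes from their 6-library mean in log2 CPM (horizontal axis); grey is vehicle, red is LXR agonist, and symbols mark replicates 1 to 3. Vehicle libraries span -1.82 to 1.17 for fibroblasts and matrix, agonist replicate 3 stands at 1.68 for basal and myoepithelial cells, and scores of the groups overlap in every row.

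In total camera called 17 of the 33 lists with its preset correlation, 12 higher and 5 lower with agonist. With the correlation estimated from these libraries 0 were called, with 1 list at an unadjusted p under 0.05, the B and plasma cells (0.0437). Fry called 0, with a smallest adjusted p of 0.764 and a smallest unadjusted p of 0.0705. The exact permutation test of list scores gave no p below 0.2 (smallest possible 0.1).

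The libraries did not separate by treatment as wholes. Spearman correlations of log2 CPM across genes, which are not independent replicates, were 0.974 to 0.982 among agonist libraries, 0.954 to 0.969 among vehicle libraries and 0.964 to 0.982 between the groups. Vehicle replicate 2 had a mean correlation of 0.980 with the agonist libraries and 0.957 with the other vehicle libraries, a difference of 0.0232, against 0.0032 and 0.00553 for vehicle replicates 1 and 3. The first principal component of the 500 most variable genes took 32.3% of the variance and set vehicle replicate 2 (-30.1) against vehicle replicate 3 (33.6), with the agonist libraries between -12.4 and -3.77. One ribosomal RNA row, CT010467.1, took 5.55% of the counts in vehicle replicate 2 and 0.112% to 0.247% in the other 5 libraries.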

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

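The GC correction, the removal of the ribosomal RNA row and the fibroblast score as a covariate were chosen after seeing the data. The count of 0 genes by edgeR held under every scaling, filter, left-out library and covariate run and at an adjusted p of 0.1. Limma-voom and limma-trend also called 0, while DESeq2 called 5 genes and 1 list member. Genes at an unadjusted p under 0.05, 538 by edgeR, numbered 847 without a low-count filter, where more genes are tested, 1210 by limma-voom, and from 315 (without agonist replicate 3) to 2442 (without vehicle replicate 2). Camera with an estimated correlation called 0 lists, with an adjusted p of 0.641 for the LXR target list, and fry called 0, with 0.764. With libraries left out the LXR list's adjusted p ran from 1.28e-05 to 0.0611 (without vehicle replicate 3). Of the 17 lists called, 4 (interferon, hypoxia, mitosis and basal genes) kept call and direction in the 15 settings that kept camera's preset correlation. Over 65 named genes 1154 of 1163 values kept direction and side of the threshold, 5 turned direction and 4 became calls, all by DESeq2. With 0 genes called by edgeR, and many genes named for a small p or for values already seen, this count shows little about stability. Over the 33 lists 414 of 561 values kept both, 36 turned, 70 lost a call and 41 gained one. The excess correlation of vehicle replicate 2 with the agonist libraries was 0.00925 without a filter and 0.0322 with the stricter one, which change the genes compared. Total counts were close across libraries, and the 26% of simulated 2-fold changes that edgeR recovered limits what a count of 0 excludes.

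The replicate numbers were not taken to pair the tumours, since nothing in the labels says that equal numbers pair them. The correlations of same-number deviations, computed afterwards, were 0.17, 0.04 and 0.06. Each library correlated best with its own number except agonist replicate 2, a hint from the data and not from the design. With a replicate block edgeR called 0 genes, with 488 at an unadjusted p under 0.05, and camera called 20 lists, 14 higher and 6 lower, with macrophages (0.00501), neutrophils (0.0241) and erythroid genes (0.0106) gained. Adipocyte genes turned under the block (adjusted p 0.597).

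The cause was not tested for any of the turns of direction that follow. The log2 fold change over left-out libraries ran from -0.37 to 0.0136 for Srebf1 (turned without agonist replicate 1) and from -0.25 to 0.056 for Nr1h3 (agonist replicate 3 or vehicle replicate 2). It ran from -1.65 to 0.96 for Csn1s2a (vehicle replicate 2) and from -0.23 to 6.21 for Bpifa2 (agonist replicate 2). Bpifa2 was chosen after its values were seen. The adjusted p of lists that turned without vehicle replicate 3 ran from 6.08e-08 to 0.183 for macrophages, 0.00582 to 0.507 for dendritic cells, 2.74e-16 to 0.545 for fibroblasts, 8.53e-05 to 0.545 for epithelial-mesenchymal transition and 0.00934 to 0.733 for cytokines. For lists that turned without vehicle replicate 1 it ran from 0.000859 to 0.368 for MHC class I, 9.96e-05 to 0.974 for MHC class II (also vehicle replicate 2), 0.0318 to 0.982 for fatty acid synthesis (also agonist replicate 2) and 0.071 to 0.989 for cholesterol synthesis (also agonist replicate 3). Milk genes (0.00173 to 0.670) also turned without vehicle replicate 1, vehicle replicate 3 or agonist replicate 2, and NRF2 targets (0.314 to 0.935) without vehicle replicate 1 or 2 or agonist replicate 1. Without agonist replicate 3 the turns were those of T and NK cells (0.00405 to 0.384), adipocytes (0.00183 to 0.690, also vehicle replicate 2) and the unfolded protein response (0.0912 to 0.908). Upper-quartile factors turned cholesterol, milk and NRF2 genes (0.978 each), fry milk genes (0.995), and the stricter filter T and NK cells (0.714). The GC correction turned milk genes (0.914) and adipocytes (0.815). The fibroblast covariate turned T and NK cells (0.996), macrophages (0.286), dendritic cells (0.736), milk genes (0.106), epithelial-mesenchymal transition (0.955) and cytokines (0.910).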

Other observations

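Chosen only after the results were seen were the tests of gene counts in other splits, of the GC correction, of a wrong label, of treatment and of salivary tissue, and the random-score control of the stroma test. Stat5a and Stat5b, neighbouring genes for the transcription factors that carry the prolactin signal in mammary epithelium, were also singled out after their values were seen. Stat5a had 59.2 ± 12.4 CPM with agonist and 98.1 ± 1.73 with vehicle (SD, 3 libraries each), a log2 fold change of -0.73 ± 0.18. Stat5b had 75.7 ± 6.64 against 113 ± 2.22 CPM (-0.58 ± 0.14). They lie side by side on chromosome 11, Stat5b at 100780731 to 100850724 on the minus strand and Stat5a at 100859351 to 100885169 on the plus strand. Both were lower in all 3 agonist libraries, with edgeR unadjusted p of 0.00376 and 0.00304 and an adjusted p of 0.99. The hypothesis that STAT5 targets were lower as a set was tested on 19 genes, 8 of them also in the milk list. Of the 18 tested, 11 were negative and 7 positive, with a median of -0.10, and camera gave p = 0.216 with the preset and p = 0.472 with an estimated correlation. A p above 0.05 had been set beforehand to count against the hypothesis, which was wrong, since a p that misses the threshold does not show that the set did not move, so the hypothesis stays undecided.

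The clustered protocadherin alpha genes, adhesion molecules whose shared exons leave single members uncertain, were also picked after their values were seen. Their 14 members summed to 2.79, 2.29 and 2.05 CPM in the agonist libraries and to 29.4, 8.26 and 9.34 CPM in the vehicle libraries, scaled to library totals.

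The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The treatment split gave 538 genes at an unadjusted p under 0.05 and the highest other 2066, with 7 of the 10 splits at 538 or more. At an adjusted p under 0.05 all 10 splits gave 0 genes, the treatment split included. Camera with its preset correlation called 17 lists for the treatment split, which 1 of the 10 reached, and 16 for the highest other. The splits with 2066 and 1936 genes both set vehicle replicate 2 with 2 agonist libraries, which points to a structure of the samples that the treatment labels do not follow. A wrong label of that library is left open here.

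Vehicle replicate 2 lay closer to the agonist libraries than to the other vehicle libraries by 0.0232 in mean Spearman correlation across genes. The tables argue against the libraries' GC trends as the whole cause, since the difference was 0.0223 after the GC correction. Stromal content of the tumour piece stays open, because regressing out the fibroblast score brought the difference to -0.00331, but 57 of 100 random scores of expression-matched genes also brought it under 0.0116 and 13 brought it as low. A mislabelled vehicle library cannot be told apart from a vehicle tumour with high LXR targets: its LXR list score was 0.318, and its Abca1 (99.9 CPM) lay near the lowest agonist value (100.2), with the other vehicle libraries at 54.3 or less, or at 93.9 against 101.1 and 53.7 when scaled to plain library totals. Its Abcg1 (24.5 CPM) lay nearer to the other vehicle libraries (22.3 or less) than to the lowest agonist value (30.7).

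Log2 fold changes fell with the GC content of the transcript, with a Spearman correlation of -0.474 across 10646 expressed genes, which are not independent replicates, and medians from 0.13 in the low-GC to -0.18 in the high-GC group of genes (median GC 42.7% and 57.9%). Transcript length as the cause is argued against by a correlation of -0.504 with length regressed out. Vehicle replicate 1, whose own deviations rose with GC (0.509), is argued against as the whole cause by a correlation of -0.287 without it. LXR agonist treatment cannot be told apart from a technical difference between the libraries, because one that follows the groups would look the same. The GC trends of the agonist libraries (-0.22, -0.13 and -0.40) all lay below those of the vehicle libraries (0.51, -0.093 and 0.063). The exact permutation test of these trends gave p = 0.1, the smallest that 3 against 3 libraries allow. After the GC correction 16 lists were called, with the MHC class I, luminal, immediate early and mitochondrial lists lost and macrophages, neutrophils and keratinocytes gained.

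Exocrine gland transcripts, picked after their values were seen, were high in agonist replicate 2, with Pip at 1021 CPM of the library total against 3.12 to 9.80 elsewhere and a median log2 ratio to the other 5 libraries of 3.83 over 7 genes, where reads shared among Dcpp copies are uncertain. Plasma cell genes were high there too (3.47 over 3 genes), and Dcpp1 was at 102 CPM there, 30.8 in agonist replicate 3 and 12.2 in vehicle replicate 2. Parotid or submandibular tissue is argued against, since genes abundant in those glands had a median log2 ratio of 0.259 over the 6 of 8 above the floor (SD 1.12), 3.57 below the exocrine genes, with Amy1 at 8.19 CPM against 3.85 to 11.1 elsewhere. LXR agonist treatment stays open, as the exact permutation test of the exocrine score gave p = 0.2, with agonist replicates at -0.51, 5.60 and 2.0 and vehicle replicates at -0.70, 0.25 and -0.77. Other glands, and expression by the tumour cells themselves, were not tested.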
